A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

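RNA from baker's yeast was hybridised to 4 single-colour (Cy3) Agilent yeast arrays: strains A and B, each stored either refrigerated or frozen before the dough-like fermentation, with 1 array per group. The labels do not say whether each RNA sample came from 1 culture or from several. Per the file headers, the scanner images were read with Agilent Feature Extraction 10.7.3.1, which gave each spot an intensity on a linear scale that was background-subtracted and corrected for spatial and multiplicative trends, with a surrogate value where the signal did not exceed the background error. The deposited value table holds a linear ratio: each column equalled the array's processed signal divided by 1 constant close to the 75th percentile of all its spots, with genes not centred and no log taken. Its column medians were 0.295 for refrigerated strain A, 0.283 for refrigerated strain B, 0.264 for frozen strain A and 0.266 for frozen strain B, and it served as an alternative. The labels do not say how that constant was chosen.

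Each array held 13048 spots, of which 12512 measured genes and 536 were controls, with 2 spots for each of 6256 gene probes. Control spots and spots that Feature Extraction marked as outliers were left out, the log2 of the processed signal was taken, the array's 75th percentile over gene spots was subtracted, and the spots of a probe were averaged. Of the probes, 5765 matched the reference gene table of assembly R64 by systematic name or accession and took its current symbols, and 491 kept the name the files give. Gene positions come from the same table. For the 5646 probes whose descriptions in the files give a position on release 64-1-1, 5367 gave both ends as the table does and the other 279 gave 1 end. Where a locus had several probes, the brightest was used: this touched 29 loci, and among the 27 with several bright probes the median disagreement of their freezing ratios was 0.0890 log2 and the largest 0.690. Probes of near-identical genes can bind each other's transcripts, so HSP82 and HSC82, SSA1 and SSA2, MAL12 and MAL32, HXT6 and HXT7, the CUP1 copies, and the FLO and PAU families are uncertain as single genes.

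A probe counted as above background on an array when both of its spots were well above background by Feature Extraction, and a gene was tested when its probe was above background on at least 2 of the 4 arrays. This kept 5887 of 6225 loci and left out 338; 5711 were above background on all 4 arrays. The spread between the 2 spots of a probe gave an SD of 0.0871 to 0.0968 log2 per array, and a technical SD of 0.0942 for a ratio of 2 arrays, which covers neither culture nor RNA preparation. The number of arrays limits the precision. Where a probe was above background in every array of 1 group of arrays and in none of the other, the fold is a lower bound. It sets the bright group's mean log2 value against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among probes above background.

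No group has a replicate. Frozen and refrigerated storage were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3) in an additive model of strain and storage over all 4 arrays, in which the strains stand in for replicates of the storage effect and strain is a block. The same fit gave the difference between strains. It leaves 1 residual degree of freedom (2.72 prior degrees of freedom), the tests were two-sided, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The block comes from the labels, which put each strain in both storages; deviations of the same strain from the storage means correlated at 0.812 across genes. Ratios within 1 strain have no test and were counted at 2-fold or more. The difference between the strains in their response to storage cannot be tested, since it is the residual of the fit.

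For 42 lists of genes, written down with the rest of the design before the data were examined, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. Member genes past the threshold were counted with p-values adjusted over all genes and adjusted over the list alone. Names in the lists were matched to current symbols, then to older names held by 1 gene only. Genes named in the text were fixed by rule: among genes above background on all 4 arrays, the 12 higher and 12 lower after freezing with the largest smaller ratio of the 2 strains, the 10 each way between strains by the same rule over the storages, the 6 each way with the largest difference in response, the 2 highest and 2 lowest of a described list, the 5 largest lower bounds each way for storage, and a panel of 20 genes. Other genes are named where the text says they were chosen after their values were seen.

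The fit was tested on simulated data with 5887 genes and 200 of them changed. For the storage comparison it recovered 1.49% of 67 genes changed 2-fold, 89.6% of 67 changed 4-fold and 98.5% of 66 changed 8-fold, with 13 false calls. For the strain comparison it recovered 1.49% of 67 genes at 2-fold, 82.1% of 67 at 4-fold and 93.9% of 66 at 8-fold, with 4 false calls. The 13 false calls for storage stood beside 1, 60 and 65 genes recovered at 2-, 4- and 8-fold. These rates hold for the simulated changes only. On the real arrays SPS100 (mean 12.0-fold higher), SSA2 (9.38-fold lower) and HSP82 (7.59-fold lower) were not called for storage. Of 200 simulated lists of 25 genes, 5% of those with no shift fell outside the central 95% of random lists and 100% of those shifted by 0.5 log2 did so.

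Alternatives covered the scaling (array median, quantile, the 75th percentile over bright probes, spike-in controls, the deposited ratios), the background (normexp with an offset of 50), the filters on dim and outlier spots, the use of a gene's several probes, the prior, the block, the thresholds and leaving out each array in turn, the last in the fit without the block, since 3 arrays leave the additive model no residual degree of freedom. All 4 arrays lay on 1 slide read in 1 scan, so neither could act as a batch; the array of frozen strain B lay in another line of the slide than the other 3. Plots were drawn with matplotlib 3.10.9.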

Results

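Gene expression was measured in 2 strains of baker's yeast (Saccharomyces cerevisiae), called strain A and strain B, shortly after stored cells were put back to work. Baker's yeast is sold as a pressed wet mass that is kept cold or frozen, and ice formation during frozen storage damages membranes and proteins. The cells had been kept for 2 weeks at 4 °C (refrigerated) or at -20 °C (frozen). Then 0.4 g was placed in 30 mL of a liquid medium that imitates bread dough, with sucrose as the sugar and urea and ammonium as nitrogen sources, and harvested after 30 min at 30 °C. There was 1 array for each of the 4 combinations of strain and storage, and no array of cells that had not been stored, so a transcript higher after freezing can also be called lower after refrigeration.

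Of 6256 gene probes, 5855 (93.6%) were above background in refrigerated strain A, 5870 (93.8%) in refrigerated strain B, 5852 (93.5%) in frozen strain A and 5868 (93.8%) in frozen strain B. The 75th percentile of the signal was 2220, 2942, 2326 and 2553 in the same order, and no spot was saturated (0 on each array). Across genes, the storages of 1 strain correlated more closely (0.980 in strain A, 0.973 in strain B) than the strains did within a storage (0.950 refrigerated, 0.956 frozen); genes are not independent replicates.

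The first comparison asked which transcripts differ during early dough fermentation between cells stored frozen and cells stored refrigerated. Frozen storage leaves cells with injured membranes, oxidised components and misfolded proteins, and the transcripts made on return to warmth show which repair and supply systems they call on. In both strains, stress and fat-burning genes were higher after freezing, and protein-folding and protein-degrading machinery was lower. Other lists, given below, differed between the strains. In strain A, 170 genes were at least 2-fold higher and 303 at least 2-fold lower after freezing; in strain B, 298 were higher and 283 lower. These balances turned with the scaling: strain A had 229 higher and 211 lower with arrays scaled to their medians, and 224 and 199 with quantile normalization. Strain B had 217 higher and 512 lower with spike-in scaling. Both strains shared 128 genes higher and 114 lower (117 and 151 with spike-in scaling), where independent lists of these sizes would share 8.61 and 14.6, and 8 genes passed 2-fold in opposite directions. The ratios of the 2 strains correlated across genes (Pearson 0.638, Spearman 0.579), and 72.9% of the 5887 genes had the same sign in both. No single gene passed limma's threshold over all genes: 0 were called, the smallest adjusted p was 0.0641, shared by 95 genes, and 1423 genes (495 higher, 928 lower) had an unadjusted p under 0.05. That 0 depended on the scaling and the prior, with 308 calls after quantile normalization, 222 after spike-in scaling, 101 after scaling to bright probes, 407 with normexp background and 182 with an intensity trend in the prior. Calls adjusted over a list alone, given below, depended on strain as a block: summed over the 42 lists, limma gave 207 with it and 49 without.

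The 12 genes highest after freezing in both strains were of several kinds. SPS100 (YHR139C, chromosome VIII, 378219 to 379199), which encodes a spore-wall protein, was higher by 2.86 log2 in strain A and 4.32 in strain B, with a mean of 3.59 and a limma standard error of 0.40. GRE1 (YPL223C), a hydrophilin that protects proteins from drying, was higher by 2.32 and 3.50, and an unnamed transcript (TC21215) by 2.71 and 3.67. The small heat-shock protein gene HSP26 (YBR072W, chromosome II, 382030 to 382674) was higher by 2.26 in strain A and 2.31 in strain B. DDR2 (2.22 and 2.87) is a marker of the general stress response, and RGI2 (2.29 and 3.24) is a gene of respiratory growth. FMP16 (2.30 and 2.97), MSC1 (2.36 and 2.10) and IRC24 (2.09 and 2.39) are stress-induced genes of little-known function. POT1 (2.15 and 2.65) carries out the last step of fatty acid oxidation, FAT3 (2.13 and 2.47) takes part in fatty acid uptake, and CHA1 (2.13 and 2.19) breaks down serine and threonine. With limma, the adjusted p of these 12 genes lay between 0.0641 and 0.0676.

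The 12 genes lowest after freezing in both strains included chaperones and their helpers. HSP82 (YPL240C, chromosome XVI, 96496 to 98625), the stress-inducible form of the chaperone that matures kinases and receptors, was lower by -2.94 log2 in strain A and -2.91 in strain B, with a standard error of 0.14. Its co-chaperones followed: AHA1 (mean -3.11) activates it, and CPR6 (-2.47 and -2.33) binds it as a peptidyl-prolyl isomerase. The folding chaperones SSA2 (YLL024C, -2.67 and -3.79) and SSA4 (-2.97 and -2.25) were lower as well. HXT8 (YJL214W), a little-studied member of the hexose transporter family, was lower by -3.03 and -2.95. UGA1 (-1.97 and -2.61) acts in the use of GABA as a nitrogen source, SRL3 (-2.03 and -2.02) and CIP1 (-2.49 and -2.01) act in cell-cycle control, and MGA1 (-2.88 and -1.90) resembles heat-shock factor. PRM4 (-2.56 and -2.54) and YJR115W (-1.90 and -1.82) complete the 12 genes, whose adjusted p in limma ran from 0.0641 to 0.0677.

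**Figure D1:**
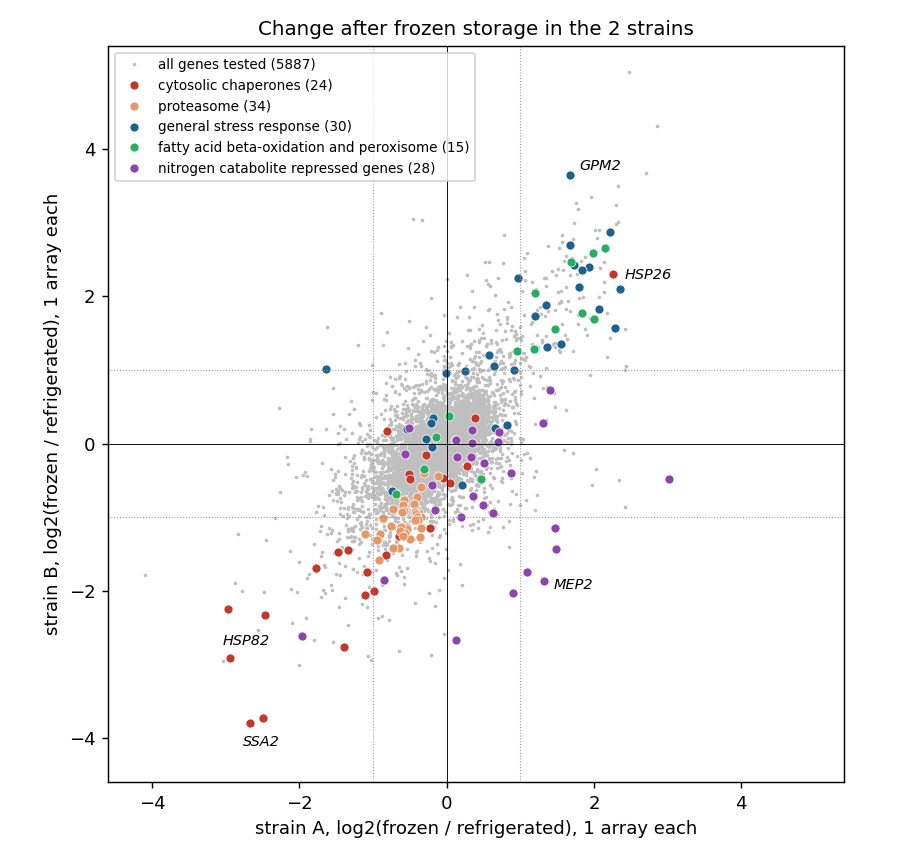
Each point is a gene, placed by the log2 ratio of frozen to refrigerated storage in strain A (x) and strain B (y), with dotted lines at 2-fold and 5 gene lists in colour. Chaperones lie to the lower left (medians -0.91 and -1.46), stress genes to the upper right (0.94 and 1.25) and nitrogen-repressed genes to the lower right (0.42 and -0.52).

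Protein folding and protein degradation went the same way. Chaperones keep damaged proteins soluble, and the proteasome with its ubiquitin tags destroys those beyond repair; both systems are normally raised together by proteotoxic stress. Among 24 cytosolic chaperone genes the median ratio was -0.91 log2 in strain A and -1.46 in strain B, below all 10000 matched random lists in each strain (percentile 0). With limma, adjusted over the list alone, 15 fell and 1 rose. SSA2 and AHA1 fell most (adjusted p 0.0027 and 0.0031 by limma over the list alone), HSP26 was the 1 that rose (0.0011), and SSA3 was higher without passing (0.38 in strain A and 0.35 in strain B). HSP104, which pulls proteins out of aggregates, was lower by -1.47 in both strains. All 34 proteasome genes measured were below 0 in both strains, with medians of -0.55 and -1.04 (percentile 0 in each). By limma, adjusted over the list alone, 32 of them fell, but with arrays scaled to their medians 0 did. RPT1 (-0.92 and -1.58) and PRE1 (-1.11 and -1.23) were lowest, and PRE9 (-0.13 and -0.44) and PRE7 (-0.31 and -0.40) moved least. Ubiquitin genes had medians of -0.45 and -0.44, with NPL4 and CDC48, which extract tagged proteins, lowest (-0.95 and -1.35, -1.05 and -1.11). Mitochondrial chaperones had medians of -0.21 in strain A, inside the range of random lists, and -0.31 in strain B, below it. By limma adjusted over the list alone 2 of 10 fell, and HSP78 (-1.34 and -2.46) was lowest. Endoplasmic reticulum folding genes of the unfolded protein response lay inside the range of random lists, with medians of -0.22 and -0.17, though DER1 (-1.45 and -0.95) and HRD1 (-1.34 and -1.16) of the disposal pathway fell by limma adjusted over the list alone (adjusted p 0.038 and 0.027). The polyubiquitin gene UBI4 was lower by -0.33 and -0.67 and did not pass.

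The general stress response covers genes switched on by many stresses and by slow growth, and in contrast to the chaperones it was higher. Its 30 genes had medians of 0.94 log2 in strain A and 1.25 in strain B (percentile 100 in each), 14 were at least 2-fold higher in both strains, and by limma adjusted over the list alone 18 rose and 1 fell. The phosphoglycerate mutase homologue GPM2 (1.67 and 3.64) and DDR2 rose most, PNS1 (-0.74 and -0.65) fell, and the kinase gene MRK1 went opposite ways (-1.64 and 1.01). HSP12, a membrane-protecting protein, was higher by 2.07 and 1.83, and the catalase gene CTT1 by 1.73 and 2.42. Oxidative stress genes as a list lay inside the random range (medians -0.01 and -0.09), while their members split: GTT1 (1.88 and 2.54) and the mitochondrial superoxide dismutase gene SOD2 (1.34 and 2.14) rose, and the peroxiredoxin genes AHP1 (-0.77 and -1.26) and TSA2 (-0.72 and -1.15) fell, each by limma adjusted over the list alone, though AHP1 and TSA2 did not with arrays scaled to their medians, nor TSA2 with quantile normalization. Trehalose and glycogen are storage sugars, and trehalose guards membranes in frozen cells. TSL1 (1.34 and 1.84), a subunit of trehalose synthase, and the trehalase gene ATH1 (1.22 and 1.71) rose by limma adjusted over the list alone, and TPS3 (-0.79 and -0.51), another subunit of the synthase, fell, a call lost with arrays scaled to their medians, quantile normalization, normexp background and an intensity trend in the prior. The synthase gene TPS1 (0.14 and 0.32) and the trehalase gene NTH1 (-0.03 and 0.41) were close to 0. For glycogen, 4 of 13 genes rose and 1 fell by the same test: the breakdown enzymes GPH1 (1.57 and 2.74) and GDB1 (0.82 and 1.69) rose, and the primer GLG1 (-1.14 and -1.78) fell. The synthase gene GSY2 (0.80 and 1.53), chosen after its values were seen, rose too. Glycerol and osmotic stress genes were slightly higher (medians 0.17 and 0.36): GRE1 and the glycerol synthesis gene GPD1 (0.87 and 1.86) rose and YJL107C (-1.27 and -1.14) fell by limma adjusted over the list alone, though GPD1 did not with no filter on dim probes or with genes bright on all 4 arrays.

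Genes for burning fat and non-sugar carbon were higher after freezing although the medium held sucrose, and these genes are normally repressed by sugar. Fatty acid oxidation and peroxisome genes had the largest median of all lists, 1.19 in strain A and 1.28 in strain B, and by limma adjusted over the list alone 9 of 15 rose and 1 fell. POT1 and FOX2 (1.99 and 2.59), 2 enzymes of the pathway, rose most, and its activators OAF1 (-0.68 and -0.68) and PIP2 (-0.31 and -0.35) were lowest. The tricarboxylic acid cycle had medians of 0.76 and 1.02 with 9 of 14 genes risen by the same test, led by MDH1 (1.35 and 2.25) and CIT3 (1.68 and 1.80). In the gluconeogenesis and glyoxylate list (medians 0.65 and 0.77) 13 of 22 genes rose and 5 fell. The alcohol dehydrogenase gene ADH2 (1.52 and 2.37), which consumes ethanol, and the acetate transporter gene ADY2 (1.90 and 1.48) rose most, and the carnitine carrier CRC1 (-1.53 and -1.49) and REG2 (-1.08 and -2.22) fell most. Respiration genes had medians of 0.26 and 0.91 with 27 of 38 above 0 in both strains, though by limma adjusted over the list alone only NDE2 (2.14 and 2.06) rose; 14 did with quantile normalization and 17 with normexp background. CYC1 (-1.32 and -0.24) and COX5B (-0.89 and -1.05), the low-oxygen subunit, were lowest. Vacuole and autophagy genes, which recycle cell contents, had medians of 0.55 and 0.65, with the carboxypeptidase genes PRC1 (1.52 and 2.66) and CPS1 (2.18 and 1.77) highest, and by limma adjusted over the list alone 9 of 20 rose and 1 fell. With spike-in scaling, scaling to bright probes or no filter on dim probes 6 rose, and the last 2 of these, median scaling and quantile normalization left 0 fallen.

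Glycolysis and ethanol formation differed less. Hexose transport genes went both ways, and by limma adjusted over the list alone 3 of 14 rose and 3 fell. In the glycolysis list the medians were -0.08 and 0.07 and 0 genes passed adjusted over the list alone by limma. Small as it was, strain A's median lay below the range of random lists matched on expression (percentile 0.03). Strain B's lay inside it (percentile 5.4). The sign of the list's median over the strains, 0.03, turned to -0.05 with quantile normalization and -0.09 with spike-in scaling. ADH1 (-0.03 and 0.07) and PDC1 (-0.05 and 0.13), the main genes of ethanol formation, lay near 0, and the sign of their mean turned with the same scalings. Among hexose transporters, HXT5 (1.76 and 2.30), made in slow growth, HXT6 (0.92 and 1.53) and the high-affinity HXT7 (0.94 and 1.49) were higher. HXT8 and the glucose-repression gene MTH1 (-2.01 and -1.60) fell by limma adjusted over the list alone, and the low-affinity HXT1 (0.18 and -0.03) lay near 0, with a mean whose sign turned with quantile normalization and spike-in scaling. The invertase gene SUC2, whose enzyme splits the sucrose of the medium, was lower in strain A (-0.76) and higher in strain B (0.29). Maltase genes MAL32 (2.34 and -0.50) and MAL12 (2.03 and -0.34) were higher in strain A alone, and the isomaltase gene IMA1 (-1.41 and -0.98) fell by limma adjusted over the list alone.

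Growth machinery bears on whether cells have restarted. All 65 ribosome biogenesis genes were above 0 in both strains, by medians of 0.35 in strain A and 0.39 in strain B (percentile 100 in each; 0.16 in strain B with spike-in scaling and 0.20 in strain A with quantile normalization), with DBP2 (0.84 and 1.21) and RPA12 (0.44 and 1.01) highest; by limma, 0 passed adjusted over the list alone. Cytosolic ribosomal protein genes had medians of 0.13 and 0.33, with 117 of 137 above 0 in both. Strain A's median lay inside the range of random lists (percentile 4.04) and turned to -0.00 with quantile normalization, and strain B's was 0.10 with spike-in scaling. RPL3 was higher by 0.03 and 0.23, and its mean turned to -0.03 with quantile normalization. Genes of late mitosis and cell separation were higher (medians 0.18 and 0.48), and 7 of 23 rose by limma adjusted over the list alone, among them DSE4 (1.30 and 1.38) and EGT2 (1.95 and 0.93, not called with spike-in scaling), which separate daughter from mother.

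Membrane and vitamin genes split within their lists. INO1 (2.21 and 1.43), the first enzyme of inositol synthesis, and OPI3 (0.93 and 1.14) of phosphatidylcholine synthesis rose, and the choline kinase gene CKI1 (-1.46 and -1.21) and FAA4 (-0.69 and -1.14) fell, by limma adjusted over the list alone, FAA4 not with arrays scaled to their medians. Fatty acid desaturase OLE1, which keeps membranes fluid in the cold, was lower by -0.48 and -1.05 without passing. In the list of vitamin B1 and B6 genes, 7 of 20 rose (3 with normexp background) and 7 fell by the same test: the thiamine synthesis gene THI4 (1.35 and 1.46) rose, and the thiamine regulator THI2 (-1.66 and -1.68) and transporter THI7 (-1.66 and -2.03) fell. Cell wall genes were lower by medians of -0.29 and -0.13, with PIR3 (-1.01 and -1.75) and CWP1 (-0.91 and -0.85) fallen, except with arrays scaled to their medians or with no filter on dim probes, and the glucan synthase gene GSC2 (1.47 and 1.37) risen. Exporters of drugs and weak acids were lower by medians of -0.40 and -0.55, where the polyamine exporter genes TPO3 (-1.71 and -1.53) and TPO2 (-1.15 and -2.18) fell and PDR10 (1.48 and 2.28) and AQR1 (0.73 and 1.28) rose. In these 2 lists the calls are again from limma adjusted over the list alone. In the proline list, whose end product protects against freezing, PRO1 was higher by 0.39 and 0.25 and PUT1, which degrades proline, by 1.21 in strain A and -0.38 in strain B; by limma, 0 genes passed adjusted over the list alone.

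Across the 42 lists, 10 had medians above the central 95% of matched random lists in both strains, 5 lay below it in both, 3 lay above in 1 strain and below in the other, 16 lay outside in 1 strain only and 8 lay inside in both. The mean of a list had the opposite sign to its median in 4 lists in strain A: trehalose metabolism (mean 0.19), oxidative stress defence (0.13), glycolysis (0.02) and vitamin B1 and B6 synthesis (-0.08). In strain B the same held for oxidative stress defence (0.03), ergosterol biosynthesis (-0.02), fatty acid and phospholipid synthesis (-0.02) and the phosphate response (0.08).

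**Figure D2:**
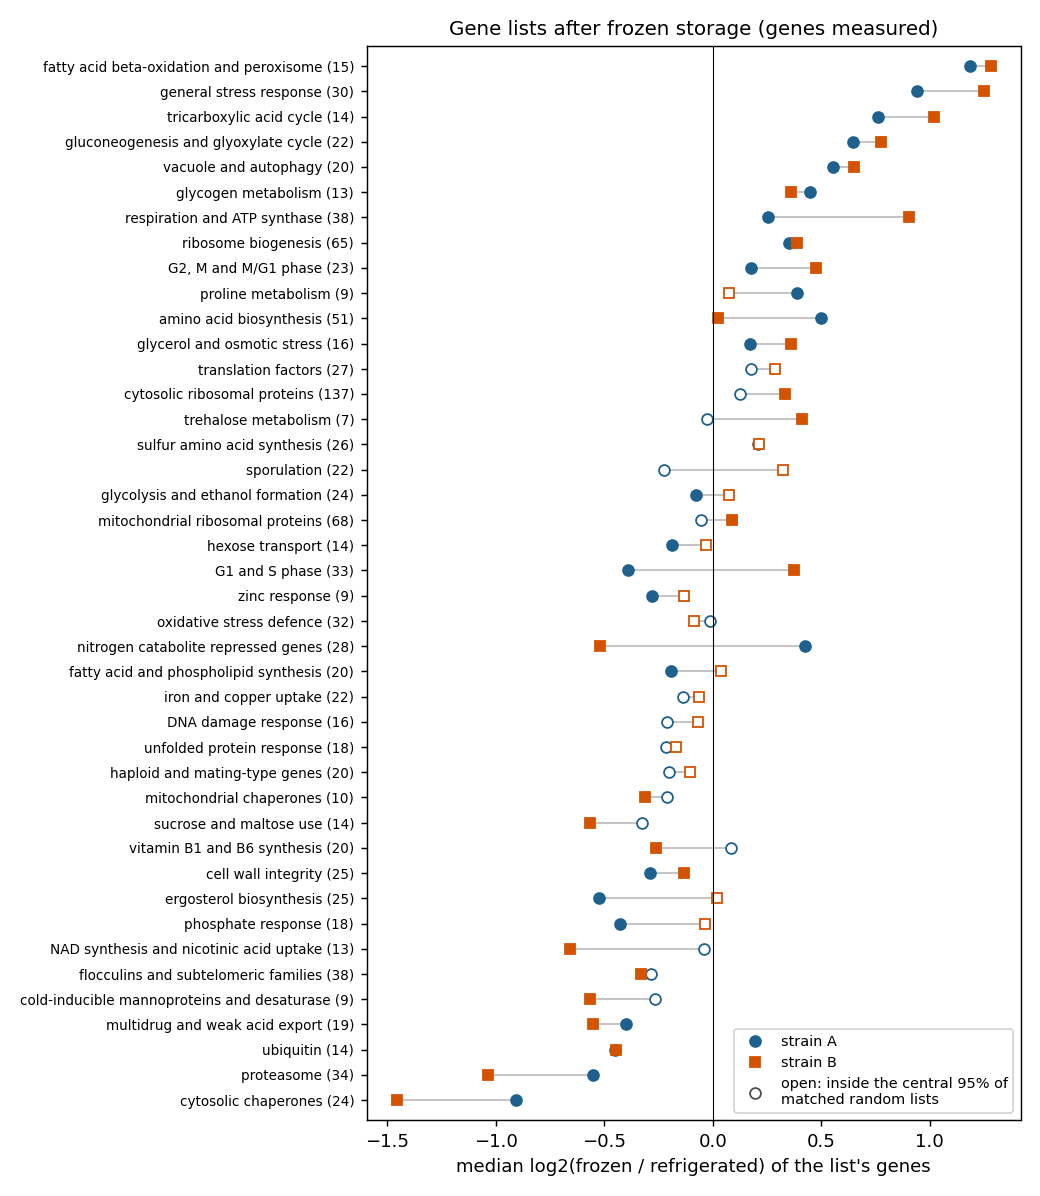
Median log2 ratio of frozen to refrigerated storage for each of the 42 gene lists, as circles for strain A and squares for strain B, filled where the median lies outside the central 95% of matched random lists. Fatty acid oxidation is highest (1.19 and 1.28) and cytosolic chaperones are lowest (-0.91 and -1.46).

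For genes above background in both strains after 1 storage and in neither after the other, folds are lower bounds. There were 19 such genes after freezing, 3 of them at least 2-fold, and 14 after refrigeration, also 3 at least 2-fold; all were faint. Genes higher after freezing included RMR1 (at least 2.33-fold), YIL054W (2.21), TC20762 (1.79) and OSW1 (1.75). YAL004W was at least 3.03-fold higher after refrigeration, followed by YJR020W (2.08), YLR012C (2.02), YGR139W (1.89) and YLR235C (1.67).

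The second comparison set strain B against strain A, which the labels describe only as 2 strains. A lower signal in 1 strain can come from a sequence difference under the probe or a missing gene as well as from less transcript. Strains of baker's yeast differ in what they take up, in how they stick together and in their cell walls. In refrigerated cells 283 genes were at least 2-fold higher in strain B and 335 lower, in frozen cells 303 were higher and 265 lower, and 164 were higher and 153 lower in both (14.6 and 15.1 for independent lists). By limma, 211 genes passed the threshold, 100 higher in strain B and 111 lower, but 309 and 120 with spike-in scaling. Some of the 211 were below background on both arrays of 1 strain, so the size of their ratios rests on values near the floor. Among genes above background on all 4 arrays alone, 147 passed by limma, 71 higher and 76 lower. Without storage as a block the count was 48, all of them among the 211. Calls adjusted over a list alone depended on that block too, with 200 by limma over the 42 lists and 95 without it. The chaperone and general stress lists described below kept 0 calls without it, and the glycolysis list 1.

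Amino acid permeases led the genes higher in strain B among those above background on all 4 arrays. BAP3 (YDR046C, chromosome IV, 548762 to 550576), which imports branched-chain amino acids, was higher by 5.61 log2 in refrigerated and 5.92 in frozen cells (54.3-fold, limma adjusted p 0.0034). TAT1 (4.06 and 5.50), DIP5 (4.32 and 3.40) and AGP1 (2.80 and 3.52) import aromatic, acidic and most neutral amino acids, and OPT2 (4.24 and 3.24) is an oligopeptide transporter; limma gave adjusted p from 0.0233 to 0.0304. The transcription factor gene YAP6 (mean 3.15) and the iron oxidase gene FET3 (2.95 and 2.74) passed as well (adjusted p 0.0098 and 0.0152 by limma). The flocculin genes FLO9 (2.59 and 4.48) and FLO5 (mean 3.46), whose proteins make cells clump, and the flocculin-like YFL051C (2.47 and 5.24) were higher but did not pass over all genes (limma adjusted p 0.0612, 0.0629 and 0.0844).

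Among genes above background on all 4 arrays, Q0297, a mitochondrial open reading frame, was lowest in strain B, by -7.51 and -7.87 (206-fold, limma adjusted p 0.0018). AMF1 (YOR378W, chromosome XV, 1049511 to 1051058), an ammonium transporter, was lower by -4.75 and -4.92, and ERG20, which makes the farnesyl precursor of sterols, by -3.70 and -3.14. Several wall and stress genes were among them: PIR3 (-3.69 and -4.42), PST1 (-2.71 and -2.61), the wall-stress reporter PRM5 (-2.62 and -3.16), ANS1 (-3.29 and -3.32) and GRE1 (-4.28 and -3.09). The prion gene RNQ1 (-2.97 and -2.77) and MMO1 (-3.90 and -2.85) complete the 10, all with limma adjusted p under the threshold, up to 0.0334. For GRE1 and MMO1 limma's adjusted p was 0.052 each with no filter on dim probes, so neither passed there.

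Cell wall genes as a group were lower in strain B. Their medians were -1.03 in refrigerated and -0.90 in frozen cells, 24 of 25 were below 0 in both, and 19 passed by limma adjusted over the list alone. The 1 exception was FLO11 (0.07 and 3.27), and CCW12 (-0.00 and -0.13) came next. Flocculins and subtelomeric families went the other way, with medians of 0.95 and 0.83, 34 of 38 above 0 in both storages and 32 higher by limma adjusted over the list alone; PAU17 (-0.68 and -0.36) was lower by the same test, a call lost with spike-in scaling, scaling to bright probes, no filter on dim probes and an intensity trend in the prior. Many of these probes cannot tell family members apart. Iron and copper uptake genes had medians of 0.74 and 0.63, with 9 higher and 2 lower by the same test; FRE2, a reductase gene, was lower by a mean of -2.68 and HMX1, a heme oxygenase gene, by -1.47.

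Chaperones were higher in strain B, by medians of 1.06 in refrigerated and 0.52 in frozen cells, with 11 of 24 higher by limma adjusted over the list alone. BTN2 (1.53 and 1.61) and AHA1 (2.81 and 1.59) were highest, and HSP26 was lower by a mean of -2.47. In the general stress list, whose medians were -0.06 and 0.23, HSP12 (-1.94 and -2.18) and CTT1 (-3.14 and -2.45) were lower in strain B and HXK1 (1.47 and 2.75) was higher by limma adjusted over the list alone. Glycolysis genes were lower by medians of -0.53 and -0.47 with 11 of 24 lower (3 with spike-in scaling) and 3 higher by that test; PGI1 (-1.22 and -1.41) and PDC6 (-2.53 and -1.61) were lowest, and the glucose kinase genes HXK1 and GLK1 (1.18 and 1.81) highest. Of the sucrose and maltose genes, 6 of 14 were higher by the same test, among them the maltose transporter gene MAL11 (2.12 and 1.62). Lipid genes were lower, ELO1 (-2.71 and -2.55) for fatty acid elongation and INO1 (-2.52 and -3.31) most, in a list with medians of -0.50 and -0.33. Ribosomal protein genes were lower by medians of -0.41 and -0.23, and 0 passed by limma adjusted over the list alone; over both storages their median was -0.32, but -0.08 with quantile normalization and -0.09 with spike-in scaling.

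Some genes were above background in both arrays of 1 strain and in neither of the other: 32 in strain A, of which 16 were at least 4-fold, and 34 in strain B, of which 9 were. The largest bounds, chosen after their values were seen, included open reading frames inside introns of mitochondrial genes. AI5_ALPHA and AI5_BETA were at least 2422-fold and 1628-fold higher in strain A, with BI2 at least 281-fold, while AI2, AI1 and AI3 were at least 2775-fold, 749-fold and 68.0-fold higher in strain B. Among nuclear genes, the wall mannoprotein gene HPF1 was at least 827-fold higher in strain A, CSS1 318-fold, the salt-tolerance kinase gene HAL5 130-fold and the phosphodiester transporter gene GIT1 44.5-fold. In strain B, YOR385W was at least 28.1-fold higher, the iron reductase gene FRE3 24.3-fold, the iron-binding wall protein gene FIT3 18.3-fold and the photolyase gene PHR1 7.53-fold.

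**Figure D3:**
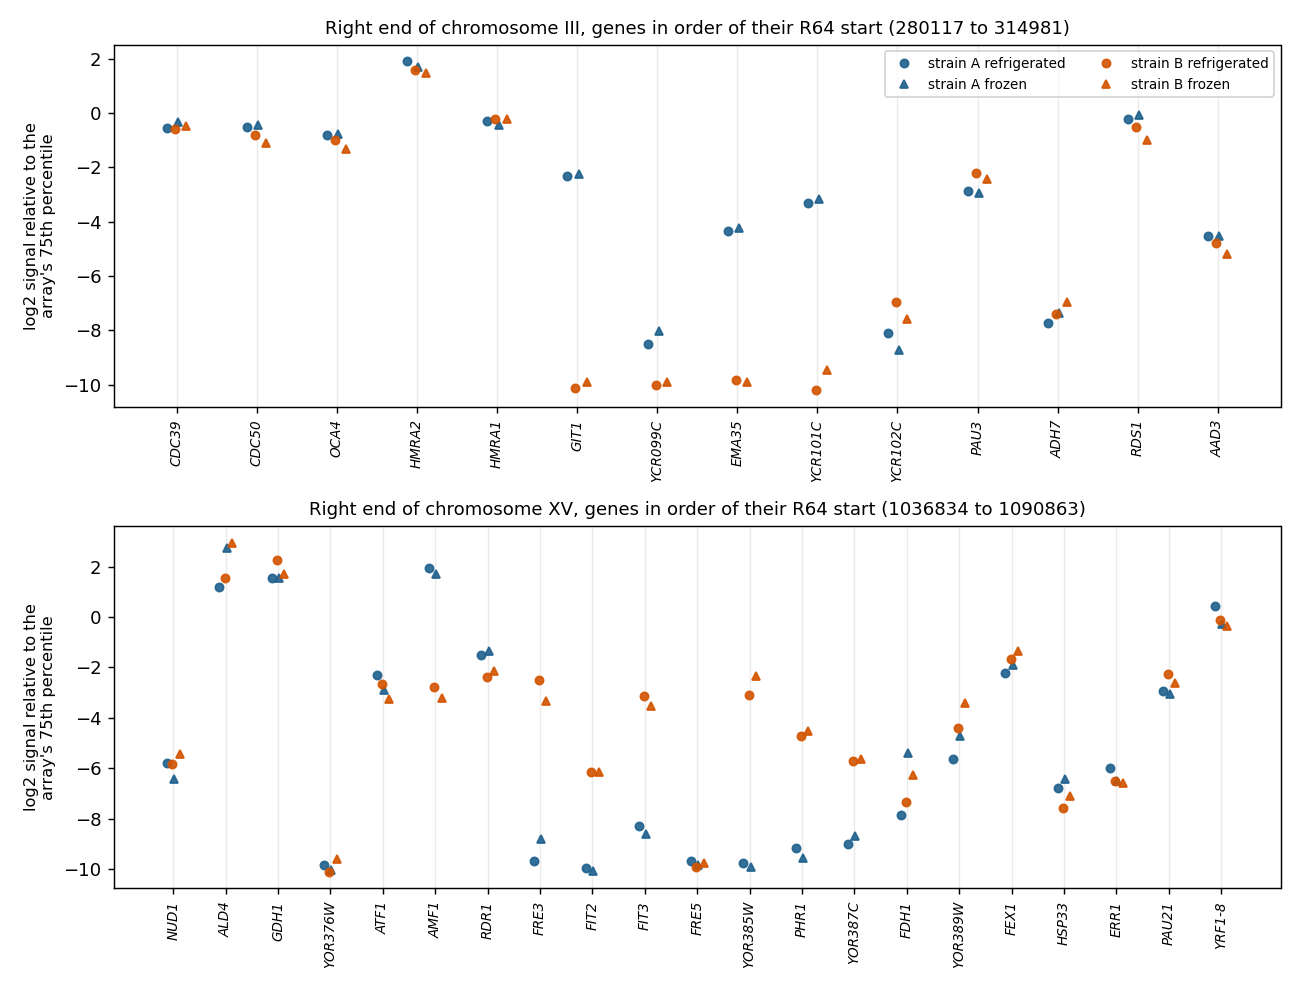
Log2 signal relative to each array's 75th percentile for every measured gene near the right ends of chromosomes III and XV, in gene order, with strain A in blue and strain B in orange, circles refrigerated and triangles frozen. GIT1 to YCR101C are dim in strain B, and FRE3 to YOR387C are dim in strain A. Within these stretches YCR099C and FRE5 are dim in both strains.

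The third comparison asked whether the strains differed in their response to freezing, since strains for frozen dough are chosen for how they stand it. It is descriptive, since the design leaves no error for it. The changes of the strains differed by at least 2-fold in 387 genes, with the change in strain B above that in strain A in 242 and below it in 145. That balance turned to 139 and 239 with spike-in scaling, 160 and 184 with quantile normalization and 83 and 88 with normexp background. Those above were led by CSR2 (-0.46 in strain A and 3.05 in strain B), an arrestin-like adaptor gene repressed by glucose, and the metal reductase gene FRE7 (-0.33 and 3.03). The flocculin genes FLO11 (-1.62 and 1.58) and YFL051C (-2.28 and 0.49), MRK1 (-1.64 and 1.01) and the glucan synthesis gene KNH1 (-1.20 and 1.34) followed. Those below were led by the meiosis inducer IME1 (2.42 and -0.87), the ammonium permease gene MEP2 (1.32 and -1.87), the allantoin-use genes DAL3 (0.89 and -2.03) and DAL7 (1.10 and -1.75), the urea transporter gene DUR3 (1.49 and -1.43) and MAL32 (2.34 and -0.50).

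Nitrogen use and the G1 and S phases were among the lists that separated the strains. Strain B's change minus strain A's had a median of 0.78 in respiration genes, with 34 of 38 above 0. In proteasome genes it was -0.52, with all 34 below 0. In genes of late mitosis and cell separation it was 0.13, inside the range of random lists (percentile 61.0). Genes repressed while good nitrogen sources are at hand had medians of 0.42 in strain A and -0.52 in strain B, and 26 of 28 had a lower change in strain B, 14 of them by at least 2-fold. AGP1 (-0.51 and 0.21) and PTR2 (-0.57 and -0.15) were the exceptions. Amino acid synthesis genes were higher after freezing in strain A (median 0.50) and close to 0 in strain B (0.03), a difference of -0.37, with 42 of 51 genes lower in their change in strain B; ARG3 (0.75 and -0.47) and ARG8 (1.04 and -0.14) of arginine synthesis differed most. Strain B's median turned to -0.11 with quantile normalization and -0.21 with spike-in scaling. Genes of DNA replication and the G1 and S phases had medians of -0.39 and 0.37; 21 of 33 were below 0 in strain A and above 0 in strain B, led by the histone gene HTA2 (-0.82 and 0.82) and the cyclin gene PCL1 (-0.84 and 0.46). Ergosterol genes were lower in strain A (median -0.53) and near 0 in strain B (0.02, but -0.21 with spike-in scaling and -0.02 with normexp background), a difference of 0.49 with 24 of 25 above 0; CYB5 (-0.70 and 0.88) and ERG5 (-1.95 and -0.43) differed most. Genes for NAD synthesis and nicotinic acid uptake had medians of -0.04 in strain A (0.10 with arrays scaled to their medians) and -0.66 in strain B, and the transporter genes TNA1 (0.01 and -1.56) and NRT1 (-0.24 and -2.03) were the lowest in their change in strain B.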

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

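The tests of an intensity bias and of a faulty array were chosen after the result was seen, as was the rule that a list with median and mean of opposite sign decides nothing; the test on further nitrogen genes was set before. The results here were picked out because freezing moved them up in 1 strain and down in the other, by more than 3 technical SDs each; with 1 array per group the difference was not tested.

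Strain B's change lay above strain A's by 3.51 log2 for CSR2, 3.36 for FRE7, 3.20 for FLO11, 2.76 for YFL051C, 2.65 for MRK1 and 2.54 for KNH1. It lay below by -3.29 for IME1, -3.20 for MEP2, -2.92 for DAL3, -2.92 for DUR3, -2.85 for DAL7 and -2.84 for MAL32. As lists, nitrogen catabolite repressed genes differed by a median of -0.89 (0.42 in strain A and -0.52 in strain B), and G1 and S phase genes by 0.73 (-0.39 and 0.37). None of these differences was tested.

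MEP2, DAL3, DUR3 and DAL7 belong to the nitrogen catabolite repressed list, which cells switch on when ammonium and other good sources run short. A bias that follows signal intensity would give random lists matched on expression the same shift, and the list's difference lay at percentile 0 of them. But the list was picked because its medians lay outside those same random lists in both strains. The outcome was thus fixed by the choice of list, and it is no separate test of such a bias. A fault of 1 array might show in the spike-in controls, whose median difference was 6.23% of the list's. That share sets spike-ins before scaling against a list after scaling, so it decides nothing. The 75th percentile minus the spike-in mean was -0.28 log2 in refrigerated and -0.29 in frozen strain A, and 0.07 and -0.16 in strain B. A fault of 1 array stays open, and so does a strain difference in nitrogen signalling. For the latter, 14 further nitrogen-repressed genes had a median difference of -0.27 log2, at percentile 0.27. Their mean was 0.03, with 9 below 0 and 5 above, so they do not decide. A difference between the 2 cultures other than the strain remains possible too, since each group has 1 array and the labels do not say whether its RNA came from 1 culture or several.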

How the results depend on the processing

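All alternatives were planned. The count of genes called after freezing, 0 by limma (1423 with an unadjusted p under 0.05), became 308 with quantile normalization, 101 with the 75th percentile over bright probes, 222 with spike-in scaling, 407 with normexp background, 182 with an intensity trend in the prior, 1 with a linear model without eBayes and 321 at an adjusted p of 0.1. It stayed at 0 with median scaling, the deposited ratios, robust eBayes, other filters, no replicate block (621 unadjusted) and, in that fit without the block, leave-one-out (0 to 0). The smallest adjusted p, 0.0641, lies close to the threshold and ranged from 0.0034 (normexp) to 0.0919 (no filter on dim probes) over the scaling and filter choices; the cause of the differences was not tested.

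Strain calls, 211, became 535 with quantile normalization, 429 with spike-in scaling, 711 with normexp background, 504 with the intensity trend in the prior and 696 at an adjusted p of 0.1. They became 147 with genes bright on all 4 arrays, 98 with no filter on dim probes and 0 with a linear model without eBayes. With no replicate block they became 48, and all 48 were shared. All 211 were kept with quantile normalization and median scaling, and 206 with spike-in scaling. Leaving out 1 array, in the fit without the block and so to be set against its 48, gave 35 to 54: 38 without refrigerated strain A, 37 without refrigerated strain B, 35 without frozen strain A and 54 without frozen strain B, where the lone array of a group is assumed to vary like the others.

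The counts at 2-fold fell with normexp background to 215 in strain A, 364 in strain B, 122 in both and 171 for the difference. By construction they moved with the size rule: 1335, 1405, 662 and 1166 at 1.5-fold, and 132, 213, 81 and 96 at 3-fold. Scaling moved the share of higher genes. In strain A it was 35.9%, but 52.0% with median scaling, 53.0% with quantile normalization and 46.5% with normexp background. In strain B it was 51.3%, but 29.8% with spike-in scaling; for genes in both strains 52.9%, but 63.9% with median scaling. Of strain calls 47.4% were higher in strain B, but 72.0% with spike-in scaling. Of genes that differed in response 62.5% were higher, but 46.5% with quantile normalization, 36.8% with spike-in scaling and 48.5% with normexp background. The median of all genes shifted by 0.14 log2 in strain A and 0.09 in strain B with median scaling, by 0.13 and 0.04 with quantile normalization, and by -0.01 and -0.23 with spike-in scaling.

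Mean freezing ratios changed sign for HXT1 (-0.0518 with quantile normalization, -0.0461 with spike-in scaling), ADH1 (-0.0537 and -0.0997), PDC1 (-0.0474 and -0.0846) and RPL3 (-0.0337 with quantile normalization), as did the median of the glycolysis list (-0.0505 and -0.0921); the cause was not tested. The medians of the chaperone, proteasome, general stress, fatty acid oxidation and cell wall lists kept their signs under every scaling. The nitrogen list kept its sign within each strain, but its median over the strains, -0.0843, turned to 0.0317 with median scaling. Without the replicate block, limma adjusted over the list alone called 2 chaperone genes fallen in place of 15, 0 proteasome genes in place of 32, 9 stress genes risen in place of 18 and 8 fatty acid oxidation genes in place of 9. It called 0 oxidative stress genes in place of 7, 0 glycogen and 0 lipid synthesis genes in place of 5 each, 0 late mitosis genes in place of 7, 2 vacuole genes in place of 10 and 2 vitamin genes in place of 14. Summed over the 42 lists this came to 49 calls in place of 207 for storage and 95 in place of 200 for strain. No slide or scan block was run, since there was 1 of each. Genes below background limit the strain comparison, where they have only bounds. Sequence differences under a probe and missing sequence limit it too, for the strain calls and the mitochondrial intron reading frames alike. The labels do not identify the strains, so this was not tested.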

Other observations

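Chosen after the result was seen were the test of a later restart, the 3 tests on genes seen in 1 strain only, and the genes of the last 2 paragraphs; the tests of RNA degradation and of intensity bias were set before, but not the rule that a trend narrower than the technical SD of a ratio decides nothing.

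After freezing, chaperone and proteasome genes were lower while general stress and fatty acid oxidation genes were higher, in both strains. Intensity bias would go with mean signal, and removing that trend left at least 99.98% of each of the 4 list medians. The trend spanned 0.49 log2 in strain A and 0.39 in strain B. In both strains the 4 lists already lay at percentile 0 or 100 of random lists matched on mean expression. Removing the trend could thus hardly move them, and it is no separate test of such a bias. It shows only that other genes of like signal did not share the shift. A later restart of growth in frozen cells would lower ribosome biogenesis genes, whose smaller strain median was 0.35 log2 above 0 (0.16 with spike-in scaling). G1 and S phase genes go with a later restart in strain A (median -0.39, percentile 0.13, 29 of 33 below 0) but not in strain B (0.37, percentile 100), so a cell-cycle delay in strain A alone stays open. RNA degradation stays open too: probes lay 60 to 304 bases from the end of their genes (5th to 95th percentile), and over that range the trend spanned at most 0.0710 log2, too little for a test. A difference in protein damage between the storages may remain as a hypothesis, untested here: with no array of unstored cells, higher chaperone transcripts after refrigeration would look the same as lower ones after freezing.

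Of 66 genes above background in 1 strain only, 43 could be placed on nuclear chromosomes, 6 were mitochondrial and 17 had no position. Signals near the detection limit would give small bounds. A bound of at least 4-fold, held by 37.9% of the genes, goes against that for those genes only. For the others it stays open: bounds reached 2-fold in 25 of the 32 genes dim in strain B and 19 of the 34 dim in strain A. Chromosome segments that 1 strain lacks are a candidate explanation for part of them: 8 pairs were neighbours, against 0.157 on average and none as many in 10000 random draws (0). These 11 genes in runs were GIT1, EMA35 and YCR101C on chromosome III and IMA2 and HPF1 on chromosome XV, dim in strain B, and FRE3, FIT2, FIT3, YOR385W, PHR1 and YOR387C on chromosome XV (1055545 to 1070241), dim in strain A. Joint regulation stays open for FRE3, FIT2 and FIT3, which respond to iron, and for the 32 isolated genes a sequence difference under a single probe could not be separated from a missing gene or a silent one.

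Amino acid permease genes split. Besides BAP3, TAT1, DIP5 and AGP1, BAP2 (1.49 log2 in refrigerated and 1.32 in frozen cells) and MUP1 (1.66 and 1.35) were higher in strain B with a limma adjusted p of 0.0419 and 0.0438, and GNP1 (2.29 and 3.69) was higher without passing (0.0535). CAN1 (mean 0.23), HIP1 (-0.25), LYP1 (-0.12) and TAT2 (0.34) were close to 0. Some iron uptake genes away from the run on chromosome XV were also higher in strain B, with means of 2.09 for FTR1, 1.97 for SIT1 and 2.07 for ARN2. But FIT1 was at 0.00, and FRE2 and HMX1, given above, were lower.

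Mitochondrial transcripts differed between the strains. COX2 (-1.67 and -1.57) and COX3 (-1.29 and -1.35), which encode subunits of cytochrome oxidase, were lower in strain B with limma adjusted p of 0.0324 and 0.0438. COX1 (-0.50 and -0.67) and VAR1 (0.98 and 1.05), a mitochondrial ribosomal protein gene, did not pass.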
